A study of Mus musculus with 6 samples.

How the data were processed

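RNA of single cells was measured in 6 libraries, 1 per embryonic stage, and the stage of each sample was taken from its label. The files hold whole-number UMI counts per gene and barcode, as the authors deposited them in matrix form, and nothing in them was normalised before deposit. The matrices were written by Cell Ranger 7.1.0, per the file headers. The submitters' processing notes name the builds mm10, GRCm38 and hg38, but the role of hg38 is not given there, and the gene identifiers in all 6 matrices are mouse. The annotation release, the alignment settings and the way barcodes were called as cells are not given in the sources used here. Each matrix has 32285 genes. Of these identifiers 32235 (99.8%) matched GENCODE M21 on GRCm38, from which gene positions were taken, and 40 symbols occur more than once and were kept apart by identifier.

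Barcodes were kept as cells with at least 1500 detected genes and at most 15% of counts from the 13 mitochondrial genes. This left 21856 of 42328 barcodes. At E5.5 68.1% of its 27302 barcodes lay under 1500 genes, and the median over all its barcodes was 1619 UMIs. Doublets were scored with Scrublet as built into scanpy, and the highest scores were removed in each library, 0.8% for each 1000 kept cells up to 8%. This removed 0, 8, 52, 242, 130 and 607 cells from E3.5 to E5.5, 1039 in all, and left 20817 cells. The number removed follows from the number of cells, not from a threshold on the score. No annotation of cells by the authors was used here.

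Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours went into Leiden clustering at resolution 1.0, which gave 30 clusters over all libraries without batch integration. Clusters were named from markers of 11 cell classes fixed before the data were examined, as were the 30 gene lists, the contrasts and the rule for naming genes. Each cluster took the class with the highest mean marker score, its log2 level over the mean of clusters. A class name needed at least 3 markers at 2-fold or more over that mean. The word like in a class name means that it rests on these markers. No cluster of a compared class had more markers of another class than of its own among its 10 leading genes, but in the trophoblast clusters 20 and 26, which hold most such cells of E4.5 and E3.5, these genes included no marker of any class. Clusters 13, 17, 18 and 29 carried markers of 2 unrelated classes and were kept out of the classes. The limit for this, a second marker score of 0.45 of the first, was set after the clusters were seen (cluster 13 stood at 0.463, and the nearest cluster below at 0.405). Clusters 24, 25 and 28 had few mitochondrial counts (medians of 0.454%, 0.666% and 0.389%).

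Within each library the counts of a class were summed and expressed as CPM, with exact Poisson intervals, where the class had at least 30 cells. The log2 ratios are of CPM plus 10, which understates the ratio of genes with few counts, while folds are plain ratios of CPM. A fold against 0 counts is a lower limit with 0 taken as 3 counts over the class, and no fold is given against 1 to 3 counts. The main contrast was E5.5 against E4.5, both filtered at 20 µm, with E5.25 against E4.75 beside it as a contrast within dissected, unfiltered embryos. E4.5 against E3.5 was a contrast within flushed embryos, and lineages were compared within libraries for 9 lists, from which any class marker was left out (1 gene, in the imprinted list). With 1 library per stage there is no replicate error, so no p-value and no count of changed genes is given.

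A gene list is summarised by the median log2 ratio of its members at 10 CPM or more in either stage, with the order-statistic interval of the median, the members at least 2-fold higher or lower, and the percentile of the median among 10000 random lists of the same size matched on mean expression. The lists were naive pluripotency, formative and primed pluripotency, primitive streak, DNA methylation, early primitive endoderm, visceral endoderm transport and secretion, anterior visceral endoderm, parietal endoderm, trophectoderm, extraembryonic ectoderm, ectoplacental cone and giant cell, glycolysis, oxidative phosphorylation, cholesterol synthesis, basement membrane, apical polarity and junctions, hypoxia response, immediate early and dissociation stress, integrated stress response, p53 targets, S phase, G2 and M phase, FGF and ERK targets, NODAL pathway, BMP pathway, WNT pathway, imprinted genes, X inactivation centre, two-cell-like, and ribosome biogenesis.

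Named genes were the 8 highest and 8 lowest log2 ratios per class among genes with at least 50 CPM in the higher stage, at least 4-fold different, at least 1.5-fold different in the same direction in E5.25 against E4.75, and at 0.2 or more of the CPM of every other class in the same library, as a guard against free RNA. Mitochondrial, ribosomal protein and haemoglobin genes and unnamed gene models were left out. Up to 4 members of each list with the largest absolute ratio were named too (some items that the rule names are not reported here), as were 5 higher and 5 lower genes for E4.5 against E3.5 without the second contrast, and 5 higher and 5 lower genes shared by epiblast, endoderm and trophoblast. Cells with a UMI of an anterior visceral endoderm gene were counted after thinning each cell to 3000 UMIs, leaving out shallower cells.

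The steps were tested on simulated counts drawn from the real summed profiles of 32285 genes, with 200 genes changed in each comparison of E5.5 with E4.5. At 2-fold or more in the right direction, 196 were recovered in the epiblast (98%), 199 in the endoderm (99.5%) and 196 in the trophoblast (98%). Of genes made 4-fold lower 50 of 53, 56 of 57 and 51 of 54 were recovered, and of those made 8-fold lower 52 of 53, 47 of 47 and 50 of 51. None of the 3078, 3721 and 3080 unchanged genes passed 2-fold. Class names were recovered for 6009 of 6260 simulated cells (96.0%). These cells were drawn from the profiles of the classes already named, without mixed or uterine epithelium-like cells. Both simulations hold counting error only, so their rates do not measure error between embryos, libraries or ways of collection.

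Alternatives were a minimum of 1000 or 2500 detected genes, at most 8% mitochondrial counts, no doublet removal, resolution 0.5 or 2.0, each library clustered alone, thinning to 6000 UMIs, the mean over cells of each cell's CPM, median-of-ratios scaling, a total without mitochondrial and ribosomal protein genes, a pseudocount of 1 CPM, and no floor or 50 CPM for list members. Added after the data were seen were mixed clusters kept in their best class, a correction for gene length, E5.25 in place of E5.5 and E4.75 in place of E4.5. Intervals of the levels in mixed clusters come from resampled cells. Random steps used seed 0 or another fixed seed. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.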

Results

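Mouse embryo cells were profiled by droplet-based single-cell RNA sequencing (10x Chromium 3' chemistry) at 6 stages that span implantation, from embryonic day 3.5 (E3.5) through E4.5, E4.75, E5.0 and E5.25 to E5.5. The embryos came from B6SJLF1/J females mated with B6CBAF1/J males, both first-generation hybrid strains. Each stage was a single library of pooled embryo cells, so no difference reported here has a replicate check and no significance test between stages was made. The deposited matrices held 42328 barcodes and 391375562 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule). The totals were 1788882 UMIs at E3.5, 12180550 at E4.5, 93447232 at E4.75, 112702098 at E5.0, 90663248 at E5.25 and 80593552 at E5.5. After filtering and doublet removal 20817 cells remained: 88, 961, 2496, 5262, 3908 and 8102 in order of stage. Their median depth was 18096 UMIs at E3.5, 10485 at E4.5, 31090 at E4.75, 17310 at E5.0, 19750 at E5.25 and 5104 at E5.5. Collection differed with stage. E3.5 and E4.5 embryos were flushed from superovulated females 4 weeks old, and the later ones were dissected from the uteri of naturally mated females 7 weeks old. Cells passed a 20 µm filter at E3.5, E4.5 and E5.5 only. Intervals in brackets are exact 95% Poisson intervals for summed counts and exact 95% binomial (Clopper-Pearson) intervals for shares, and they cover counting error only. The share that a count of 0 allows is 3 over the number of cells.

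The first question was which lineages each library held. Epiblast-like and trophoblast-like cells were found in every library, endoderm-like cells (primitive or visceral) from E4.5 on apart from 2 cells at E3.5, and trophoblast giant cell-like cells from E4.75 on in the main clustering. Primitive endoderm-like cells, the inner lining that faces the blastocoel, made up 2.27% of cells at E3.5 (2 of 88) and 43.7% [40.5, 46.9] at E4.5. By E5.5 their visceral endoderm-like successors were 15.9% [15.1, 16.7]. Giant cell-like cells, the large invasive trophoblast at the maternal interface, were 0 of 961 at E4.5, which allows a share of up to 0.312%, 0.841% at E4.75, 3.65% at E5.0 and 12.4% [11.7, 13.2] at E5.5. Parietal endoderm-like cells, which lay down Reichert's membrane, were 0.104% at E4.5, 8.37% [7.32, 9.53] at E4.75 and 5.20% [4.72, 5.70] at E5.5. Both classes depend on settings at their first stages. E4.5 held 88 giant cell-like cells when each library was clustered alone and 3 to 5 under 6 other settings. E4.75 held 14 to 23 parietal endoderm-like cells instead of 209, and 1051 to 1107 endoderm-like cells instead of 894, with another minimum of genes, a lower mitochondrial limit or no doublet removal.

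The epiblast share was 50.0% [39.1, 60.9] at E3.5, 31.1% [28.2, 34.1] at E4.5, 34.1% at E4.75, 36.5% at E5.0, 32.1% at E5.25 and 29.3% [28.3, 30.3] at E5.5. Trophoblast-like cells other than giant cells were 47.7% [37.0, 58.6] at E3.5, 24.97% [22.3, 27.8] at E4.5, 18.3% at E4.75, 15.3% at E5.0, 23.3% at E5.25 and 23.5% [22.6, 24.5] at E5.5. Trophoblast and giant cells together were 24.97% at E4.5, 18.9% at E5.0 and 35.9% [34.9, 37.0] at E5.5. The epiblast-like clusters were led by Lef1, Setbp1, Igfbp2 and Tdgf1 after E4.5 and by Bnc2, Tdgf1 and Enox1 at E4.5. Visceral endoderm-like clusters were led by Apoc2, Ttr, Apoa1 and Cubn, and the E4.5 endoderm cluster by Cubn, Lama1 and Col4a1. Trophoblast clusters after E4.5 were led by Elf5, Rhox5, Phlda2, Hand1 and Tfap2c. Cluster 20, with most E4.5 trophoblast, was led by BC051665, Ctsll3, BC053393 and Nppb. Cluster 26, with the E3.5 trophoblast, was led by Calcoco2, BC053393 and BC051665. Giant cells were led by Prl3d1, Hand1 and Cdh5, and parietal endoderm by Lama1, Col4a1 and Lamb1. The E3.5 epiblast-like cells (cluster 27, led by Calcoco2, Khdc3 and Dppa3) resembled inner cell mass, as they also held 359 CPM (counts per 1e6 counts of the class) of Gata6, the primitive endoderm factor.

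Cells whose cluster carried markers of 2 lineages were kept out of the classes. They were 0 of 88 at E3.5, 0 of 961 at E4.5, 1.16% at E4.75, 1.62% at E5.0, 1.61% at E5.25 and 13.7% [12.9, 14.4] at E5.5. A cluster was set apart where its next-best lineage reached 0.45 of the marker score of its best one, a limit chosen after the clusters were seen. With these cells kept in their best class, the endoderm share at E5.5 was 25.9%. The filter and the depth can both move these shares, since the 20 µm filter was used at E4.5 and E5.5 but not between, and 68.1% of E5.5 barcodes lay under 1500 detected genes.

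**Figure D1:**
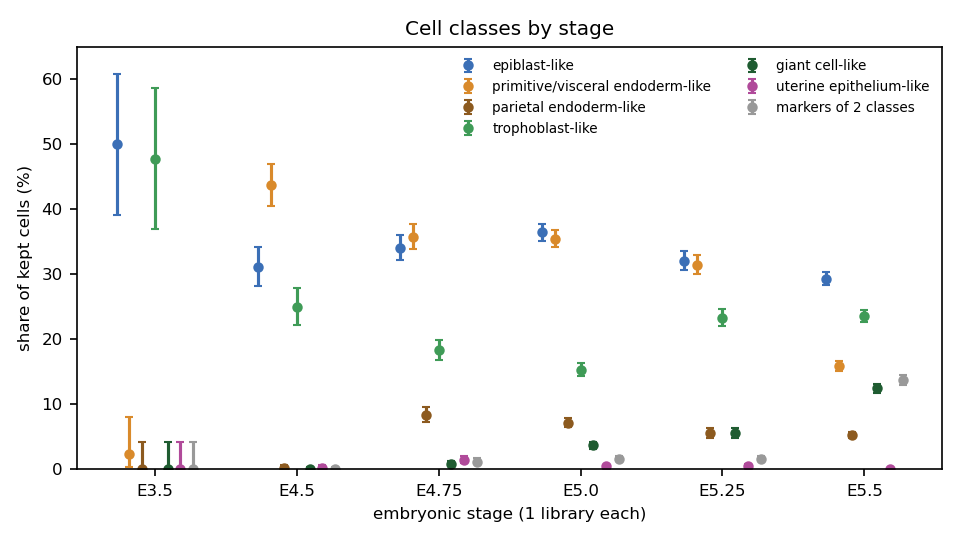
Share of kept cells in each class (y axis, percent) for the 6 libraries (x axis, embryonic day), with exact 95% binomial intervals as bars. The endoderm share is 43.7% at E4.5 and 15.9% at E5.5, and the giant cell share is 12.4% at E5.5.

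The epiblast was then compared between E4.5, before implantation, and E5.5, after it, to ask how pluripotent cells differ before and after attachment to the uterus. Naive pluripotency genes, the regulators of the ground state of the blastocyst, were lower at E5.5: 10 of 11 measured members were at least 2-fold lower and 0 were 2-fold higher. Zfp42 (Rex1), a marker of the naive state, was 214 CPM at E4.5 and 20.6 CPM at E5.5. The transcription factors Tfcp2l1 (60.9 and 2.58 CPM), Klf5 (86.1 and 12.1 CPM) and Esrrb (38.5 and 1.32 CPM) went the same way. Formative and primed genes were at least 2-fold higher in 6 of 13 members and at least 2-fold lower in 1, Lef1. The higher ones included the POU factor Pou3f1 (81.7 and 384 CPM), Sox3 (11.3 and 77.0 CPM), Sall2 (22.3 and 96.5 CPM) and the de novo DNA methyltransferase Dnmt3b (671 and 2166 CPM). Xist, the RNA that coats the inactive X chromosome, was 46.4 CPM [39.5, 54.1] at E4.5 and 944 CPM [930, 959] at E5.5, 20.4-fold higher. The E4.5 value was the lowest of the course, with 209 CPM at E3.5 and 169 CPM at E4.75. The sex of the embryos in each pool was not examined.

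As list medians, the naive list stood at a log2 ratio of −1.83 [−2.49, −1.01] between E5.5 and E4.5, where the median of all genes was 0.01. It lay below all 10000 random lists matched on expression, which describes these libraries and is not a test. The formative list stood at 0.62 [−0.34, 1.72], at percentile 98.9 of its random lists. Nanog is both a member of the naive list and an epiblast marker used to name clusters, as is Utf1 in the formative list. The epiblast class was 299 cells with 3450906 UMIs at E4.5, of which 291 cells lay in cluster 19, and 2375 cells with 16671700 UMIs at E5.5, of which 2128 lay in cluster 0. Within the dissected embryos, the naive median of E5.25 over E4.75 was −1.17, with 3 of 4 measured members at least 2-fold lower. Those classes also lay in different clusters: 766 of 851 epiblast cells at E4.75 in cluster 12, and at E5.25 582 cells in cluster 1 and 580 in cluster 3. The formative median there was −0.14, so most of its difference lay between E4.5 and E4.75: Pou3f1 was already 408 CPM and Dnmt3b 1418 CPM at E4.75. With E4.75 in place of E4.5, an alternative added after the data were seen, the naive median was −1.14 and the formative one −0.08.

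Among single genes named by a fixed rule of size, those higher in the E5.5 epiblast joined Xist with the glypican Gpc6 (34.5 and 251 CPM), Setbp1 (27.5 and 207 CPM), Bex4 (62.9 and 402 CPM), the axon guidance protein Sema6a (53.6 and 345 CPM), the carbonic anhydrase Car14 (13.3 and 118 CPM) and the LIM-domain cofactor Ldb2 (7.24 and 81.0 CPM). Fabp5, a fatty acid binding protein, was 1178 CPM at E3.5, 50.7 CPM at E4.5 and 328 CPM at E5.5. Among the genes lower at E5.5 was Mylpf, a myosin light chain of fast muscle. It was 343 CPM [324, 363] at E4.5, 270 CPM at E4.75, 79.8 CPM at E5.0, 32.7 CPM at E5.25 and 11.9 CPM [10.3, 13.7] at E5.5, 28.7-fold lower. The zinc finger gene Bnc2 was 393 and 16.9 CPM. Tdh, the threonine dehydrogenase of mouse pluripotent cells, was 162 and 10.9 CPM. Uridine phosphorylase Upp1, itself an epiblast marker, was 246 and 13.8 CPM. Enox1 (213 and 13.2 CPM), Morc1 (178 and 14.5 CPM), Fam25c (150 and 4.20 CPM) and Mfge8 (84.3 and 2.82 CPM) were lower too. Counting intervals of the named epiblast genes at their higher stage were within 1.6% to 11.7% of the value. Xist (ENSMUSG00000086503) lies on chromosome X from 103460366 to 103483254 on the minus strand, and Mylpf (ENSMUSG00000030672) on chromosome 7 from 127208890 to 127214298 on the plus strand, in GRCm38. Xist overlaps its antisense partner Tsix, and whether the counting used strand is not given in the sources used here.

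Signalling lists were compared next in the epiblast. NODAL pathway genes were lower, at a median of −1.15 [−1.91, 0.36] with 5 of 8 members at least 2-fold lower, among them the co-receptor Tdgf1 (447 and 111 CPM) and the feedback inhibitor Lefty2 (33.9 and 1.86 CPM). With E4.75 in place of E4.5 that median was −0.60. BMP pathway genes were at least 2-fold higher in 3 of 6 members (median 0.91 [−0.95, 2.30]), namely the targets Id3 (53.3 and 301 CPM), Id1 (31.9 and 132 CPM) and Id2 (18.3 and 67.4 CPM). That rests on the E4.5 library, since the median of E5.25 over E4.75 was −0.43, with 4 of 5 members lower. The FGF and ERK list was near level at −0.18, though Fgf5, the classical post-implantation epiblast gene, was 24.3 and 85.4 CPM. The WNT list was −0.39 over 4 members, with Lef1 at 408 CPM at E4.5 and 176 CPM at E5.5. The X inactivation centre list had a median of 1.24 over 5 members, where Ftx was 26.9 and 121 CPM and Jpx 6.09 and 28.0 CPM, while Tsix was 97.9 and 52.4 CPM.

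The DNA methylation list split by member. Its median was 0.06, with Dnmt3b higher but its cofactor Dnmt3l lower (382 and 80.4 CPM), as were the demethylating enzymes Tet2 (25.2 and 3.06 CPM) and Tet1 (381 and 194 CPM). Integrated stress response genes, switched on by amino acid shortage and unfolded protein, were at −1.16 [−1.76, 0.21], with 5 of 9 at least 2-fold lower, including Trib3 (60.6 and 9.06 CPM) and Chac1 (66.6 and 14.1 CPM). With E4.75 in place of E4.5 this median was −0.10. Cholesterol synthesis genes were higher than at E4.5, at 0.59 [0.22, 1.11], with Hmgcs1, an early enzyme of the pathway, at 43.8 and 162 CPM. Within the dissected embryos they went the other way, at −0.49 [−0.66, −0.28] in E5.25 over E4.75 with 17 of 17 members lower, and the median was 0.07 with E4.75 in place of E4.5. Glycolysis (−0.02) and oxidative phosphorylation (−0.16) were near level as lists, although the glucose transporter Slc2a1 was 39.4 and 177 CPM and the platelet-type phosphofructokinase Pfkp 139.96 and 18.3 CPM. The basement membrane list was −0.24, with fibronectin Fn1 at 269 and 41.4 CPM. The medians of apical polarity and junction genes (0.24), hypoxia genes (0.43, with Egln1 at 11.9 and 65.9 CPM), p53 targets (0.57), S phase (0.28) and G2 and M phase genes (0.27) had intervals that include 0, and in E5.25 over E4.75 those of S phase and of G2 and M phase were −0.17 and −0.30. Ribosome biogenesis (0.09) and imprinted genes (0.12) were near level, and 0 of the 5 genes of the two-cell-like list reached 10 CPM. Over all genes with counts at both stages the median log2 ratio of plain CPM was −0.18 in epiblast, −0.18 in trophoblast and −0.0071 in endoderm. Median-of-ratios scaling takes this off and so raises the ratios, which turned the epiblast medians of glycolysis and oxidative phosphorylation positive, so medians within that distance of 0 have no direction.

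**Figure D2:**
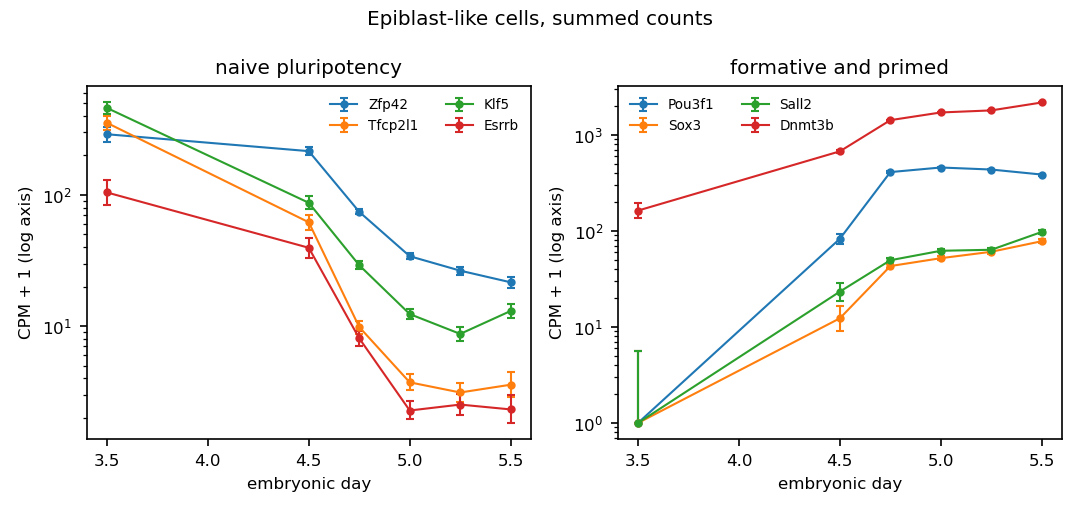
CPM plus 1 (y axis, log scale) of 4 naive genes and 4 formative genes in epiblast-like cells of each library (x axis, embryonic day), with exact 95% Poisson intervals as bars. Zfp42 is 214 CPM at E4.5 and 20.6 CPM at E5.5, while Dnmt3b is 671 and 2166 CPM.

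The endoderm was compared between the same stages, from primitive endoderm of the blastocyst to visceral endoderm of the egg cylinder. Genes of nutrient transport and secretion, the work of the visceral endoderm, were far higher at E5.5, with 9 of 13 members at least 2-fold higher and 0 at least 2-fold lower. Afp (alpha-fetoprotein) was 0.192 CPM at E4.5 (1 count) and 184 CPM [173, 194] at E5.5. The retinol carrier Rbp4 was 0.766 CPM at E4.5 and 129 CPM [120, 138] at E5.5. The apolipoproteins Apoc2 (82.2 and 1440.1 CPM), Apob (44.2 and 695 CPM) and Apoa1 (59.8 and 865 CPM; also an endoderm marker) went the same way. The imprinted gene Peg10, with the largest log2 ratio of CPM plus 10 among the named endoderm genes (5.37), was 2.68 CPM [1.47, 4.5] at E4.5 and 514 CPM [497, 532] at E5.5, 192-fold higher over 14 counts at E4.5, and already 18.3 CPM at E4.75.

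The transport list had a median of 2.10 [0.62, 3.70], above all 10000 matched random lists, against a median of 0.18 for all genes. Of its 13 members 4 are endoderm markers. In E5.25 over E4.75 it was 1.80, again with 9 of 13 members at least 2-fold higher, and 1 at least 2-fold lower. The endoderm class was 420 cells with 5221075 UMIs at E4.5, of which 418 lay in cluster 16, and 1288 cells with 6303632 UMIs at E5.5, mostly in clusters 2 (735 cells), 11 (378) and 14 (145). At E4.75 824 of 894 cells lay in cluster 10, and at E5.25 537 in cluster 2, 273 in cluster 11 and 262 in cluster 5. Nrk, an X-linked kinase, was 6.13 and 423 CPM, and Efna5, an ephrin, was 4.21 and 183 CPM. Lower at E5.5 were Glipr2 (114 and 4.60 CPM), the serine protease Htra1 (134 and 15.7 CPM), Fam25c (69.5 and 0.476 CPM), Ccser1 (58.4 and 4.76 CPM), the seryl-tRNA synthetase Sars (509 and 86.1 CPM), the translation factor Eif2s2 (2884 and 500.3 CPM) and the linker histone gene Hist1h1b (163 and 23.8 CPM). Eif2s2 has processed copies and the histones near-identical ones, so their counts are uncertain. Pou5f1, an epiblast marker, was 105 CPM in E4.5 endoderm and 15.2 CPM at E5.5, a log2 ratio of −2.18 that became 0.03 when cells needed 2500 detected genes. Counting intervals of the named endoderm genes at their higher stage were within 1.6% to 11.4% of the value. Peg10 (ENSMUSG00000092035) lies on chromosome 6 from 4747306 to 4760517 on the plus strand, and Afp (ENSMUSG00000054932) on chromosome 5 from 90490737 to 90508907 on the plus strand.

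Imprinted genes as a list were higher in E5.5 endoderm, at a median of 1.54 [0.70, 2.95] with 10 of 14 members at least 2-fold higher. Beside Peg10 these included Mest (1.72 and 94.5 CPM), H19 (105 and 876 CPM) and the growth restraint Grb10 (22.0 and 227 CPM). The median was 0.84 with E4.75 in place of E4.5. BMP pathway genes (1.65 [−0.30, 2.25]) were at least 2-fold higher in 6 of 8 members, with the ligand Bmp2 at 3.26 and 42.7 CPM. The primitive streak list was 1.37, with 5 of 5 measured members at least 2-fold higher, but 0.15 with E4.75 in place of E4.5. Of these Eomes (45.6 and 174 CPM), Gsc (0 and 15.9 CPM) and Fgf8 (13.2 and 61.7 CPM) are also active in visceral endoderm. The monocarboxylate transporter Slc16a1 was 156 and 1367 CPM, and the glycolysis list 0.41 [−0.11, 1.19]. Cholesterol synthesis was 0.58 [0.11, 0.78]. Immediate early genes were at 1.00 [0.61, 1.87] and apical junction genes at 0.62 [−0.04, 1.22], with the adhesion protein Cdh1 at 136 and 330.0 CPM, but at −0.07 in E5.25 over E4.75.

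The basement membrane list split in the endoderm, at −0.85 [−1.55, 0.97] with 5 of 11 members at least 2-fold lower and 1 higher. Lower were the laminin chains Lama1 (1246 and 419.6 CPM) and Lamb1 (911 and 285 CPM). Both are leading genes of parietal endoderm, which was 1 cell at E4.5 but a class of its own with 421 cells at E5.5. How far taking those cells out of the endoderm lowered the E5.5 values was not tested. The early primitive endoderm list was −0.40 [−1.29, 0.53], with Pdgfra at 223 and 85.5 CPM. It holds 5 endoderm markers and shares Lama1, Lamc1, Col4a1 and Col4a2 with the basement membrane list. The parietal endoderm list, which shares Lamb1, Sparc and Nid1 with the basement membrane list, was −0.39 [−1.64, 0.88] in this class. Integrated stress response genes were at −0.91 [−1.41, −0.30], with Chac1 at 67.4 and 2.54 CPM and Asns, the asparagine synthetase, at 97.1 and 38.9 CPM, but at −0.23 with E4.75 in place of E4.5. Oxidative phosphorylation genes were at −0.50 [−0.88, −0.17], with 9 of 39 at least 2-fold lower, such as Atp5e (1036 and 330.4 CPM). That direction held only against the E4.5 library: with E4.75 in its place the median was 0.03.

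The anterior visceral endoderm, the signalling centre that sets the head-to-tail axis, was looked for by its secreted inhibitors and homeobox genes. The list was higher at E5.5, at 1.37 [−0.12, 3.15] with 7 of 10 members at least 2-fold higher, among them the receptor Fzd5 (5.94 and 136 CPM) and Otx2 (8.62 and 156 CPM). Foxa2 is the only member that is also a class marker. The median was 0.35 with E4.75 in place of E4.5. Cer1, a secreted NODAL and BMP antagonist, was detected in 0.238% of endoderm-like cells at E4.5 and 6.23% [4.83, 7.89] at E5.5 after each cell was thinned to 3000 UMIs. The thinned Cer1 shares between were 0 of 891 cells at E4.75 (1.12% of 894 cells before thinning), 1.07% at E5.0 and 3.13% at E5.25.

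Thinned shares of the other genes did not follow this course. Hhex was found in 10.5% of endoderm-like cells at E4.5, 20.4% at E4.75, 13.7% at E5.0, 12.4% at E5.25 and 15.0% [12.9, 17.3] at E5.5. Lefty1 was found in 1.67% at E4.5, 10.8% at E5.25 and 6.43% at E5.5. Dkk1 was level, at 19.8% and 18.1%. In trophoblast-like cells of the E5.5 library, which should lack these genes, the thinned shares were 0.385% for Hhex, 0.330% for Lefty1, 0.440% for Dkk1 and 0 of 1819 cells for Cer1, which allows up to 0.165%. Endoderm-like cells had a median of 4347 UMIs and trophoblast-like cells 6264 at E5.5, where 261 of the 1288 endoderm cells were left out as shallower than 3000 UMIs and 1027 remained. At E4.5 the median was 10573.5 UMIs and 0 cells were left out. Unthinned shares at E4.5 and E5.5 were 34.3% and 22.1% for Hhex, 5.95% and 8.23% for Lefty1, 0.952% and 8.00% for Cer1, and 55.2% and 25.2% for Dkk1.

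The trophoblast was compared to ask how trophectoderm of the blastocyst differs from the extraembryonic ectoderm and ectoplacental cone that follow it. Phlda2, an imprinted gene that restrains placental growth, was 129.7 CPM [118, 143] at E4.5 and 1819 CPM [1797, 1841] at E5.5, 14.0-fold higher, with 228 CPM at E4.75. Ascl2, an imprinted factor of the ectoplacental cone, was 12.1 and 119.6 CPM. The water channel Aqp3 (92.3 and 4.42 CPM), the sodium pump subunit Atp1b1 (221 and 63.7 CPM), the tight junction protein Cldn4 (264 and 84.9 CPM) and the keratin Krt18 (948 and 374 CPM), all parts of the fluid-pumping trophectoderm epithelium, were lower. The trophectoderm list as a whole stood at −0.92 [−1.65, 1.10], with 5 of 11 members at least 2-fold lower and 2 higher.

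Within the dissected embryos the trophectoderm median of E5.25 over E4.75 was −1.01 [−1.27, 0.01], with 6 members at least 2-fold lower and 0 higher, while with E4.75 in place of E4.5 it was −0.56. The extraembryonic ectoderm list was 0.31 [−0.70, 1.44] at E5.5 over E4.5, percentile 79.5 of its random lists, and its members went apart: the acetyltransferase Nat8l was 4.95 and 95.8 CPM and Cdx2 28.5 and 72.7 CPM, but Bmp4 137 and 77.5 CPM. The ectoplacental cone and giant cell list was 1.13 [−1.42, 2.55], with 6 of 9 members at least 2-fold higher, but −0.10 [−0.93, 2.02] in E5.25 over E4.75. Its member Prl3d1, a placental lactogen with near-identical neighbours, was 60.7 CPM at E4.5 and 5.36 CPM at E5.5, where giant cells formed a class of their own. Of these lists 4 trophectoderm, 6 extraembryonic ectoderm and 6 cone members are class markers. The class was 240 cells with 3229375 UMIs at E4.5, of which 209 lay in cluster 20 and 23 in cluster 26, the cluster of E3.5 trophoblast. At E5.5 it was 1906 cells with 14918643 UMIs in clusters 7, 6 and 4. At E4.75 the cells were mostly in clusters 21 (199) and 22 (188), and at E5.25 in clusters 4 (623) and 6 (225). The median of all genes was 0.05.

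Other named trophoblast genes higher at E5.5 were Sox3 (0.619 and 89.7 CPM), the retinoic acid hydroxylase Cyp26a1 (2.48 and 57.5 CPM), Upp1 (9.29 and 123 CPM), the splicing factor Srsf9 (38.4 and 289 CPM) and the dUTPase Dut (187 and 901 CPM). Those lower included the tetraspanin Tspan8 (271 CPM [253, 289] and 0.469 CPM, 577-fold lower, with 86.2 CPM at E4.75), the natriuretic peptide gene Nppb (316 and 10.5 CPM) and the serpin Serpinb6c (125 and 1.34 CPM). Nppb is also a leading gene of giant cell cluster 15. Giant cells were a class of their own at E5.5 but not at E4.5, and the effect of that split was not tested. BC051665, a cathepsin-like gene, was 641 CPM at E4.5 and had 0 counts at E5.5, at least 3188-fold lower with 0 taken as 3 counts. Its neighbour Ctsll3 was 326 CPM and 0, at least 1620-fold lower. BC053393 was 330 and 0.134 CPM, Gsta1 241 and 2.28 CPM and Psg29 105 and 0.0670 CPM. Ctsll3, BC051665, Gsta1 and Psg29 belong to families of near-identical copies, so their counts are uncertain. Counting intervals of the named trophoblast genes at their higher stage were within 1.2% to 10.8% of the value. Phlda2 (ENSMUSG00000010760) lies on chromosome 7 from 143501545 to 143503150 on the minus strand, and Tspan8 (ENSMUSG00000034127) on chromosome 10 from 115816832 to 115849893 on the plus strand.

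Cholesterol synthesis genes were higher in E5.5 trophoblast, at 1.07 [0.86, 1.36] with 10 of 17 at least 2-fold higher and 0 lower, among them Hmgcs1 (29.7 and 115 CPM). The E5.25 over E4.75 median was 0.79 [0.62, 0.90]. Immediate early genes were at 1.28 [0.35, 1.85], with Fosb at 2.79 and 55.9 CPM and Fos at 50.5 and 234 CPM, and at 0.24 with E4.75 in place of E4.5. S phase (0.71 [0.23, 1.05]) and G2 and M phase genes (0.72 [0.06, 1.21]) were higher, with Mcm2 at 72.5 and 176 CPM and Ube2c at 116 and 401 CPM, but level in E5.25 over E4.75 (0.05 and 0.01). Imprinted genes were at 0.74 [0.31, 1.25], with Peg10 at 59.1 and 257 CPM. Hypoxia genes (0.73 [−0.47, 1.28]) included Ankrd37 (5.57 and 41.7 CPM), and glycolysis genes (0.50 [−0.02, 1.01]) the pyruvate dehydrogenase kinase Pdk1 (6.5 and 48.8 CPM). Integrated stress response genes were at −0.46 here and at −1.09 [−1.32, −0.67] in E5.25 over E4.75.

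**Figure D3:**
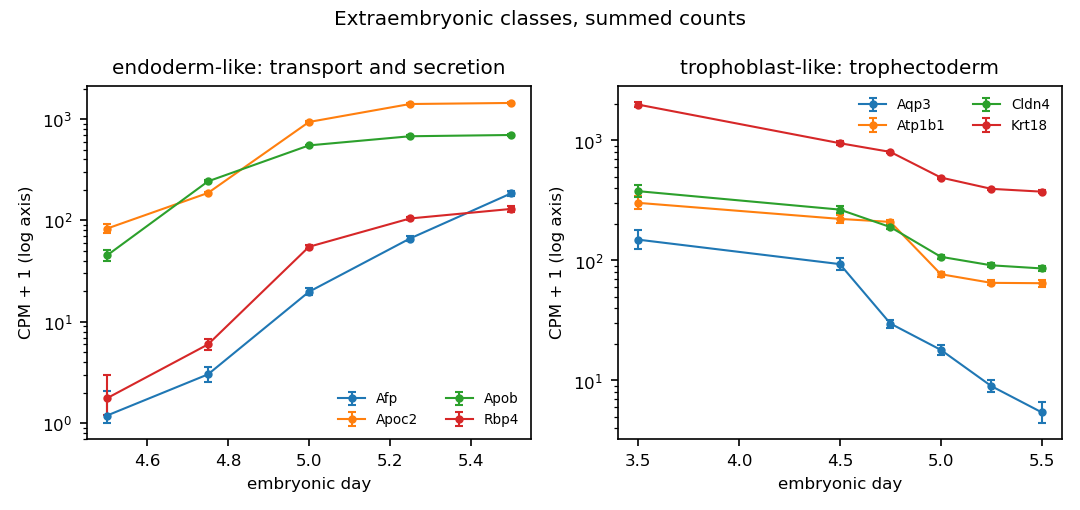
CPM plus 1 (y axis, log scale) of 4 transport genes in endoderm-like cells and of 4 trophectoderm genes in trophoblast-like cells of each library with at least 30 cells of the class (x axis, embryonic day), with exact 95% Poisson intervals as bars. Afp is 0.192 CPM at E4.5 and 184 CPM at E5.5, while Aqp3 is 92.3 and 4.42 CPM.

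**Figure D4:**
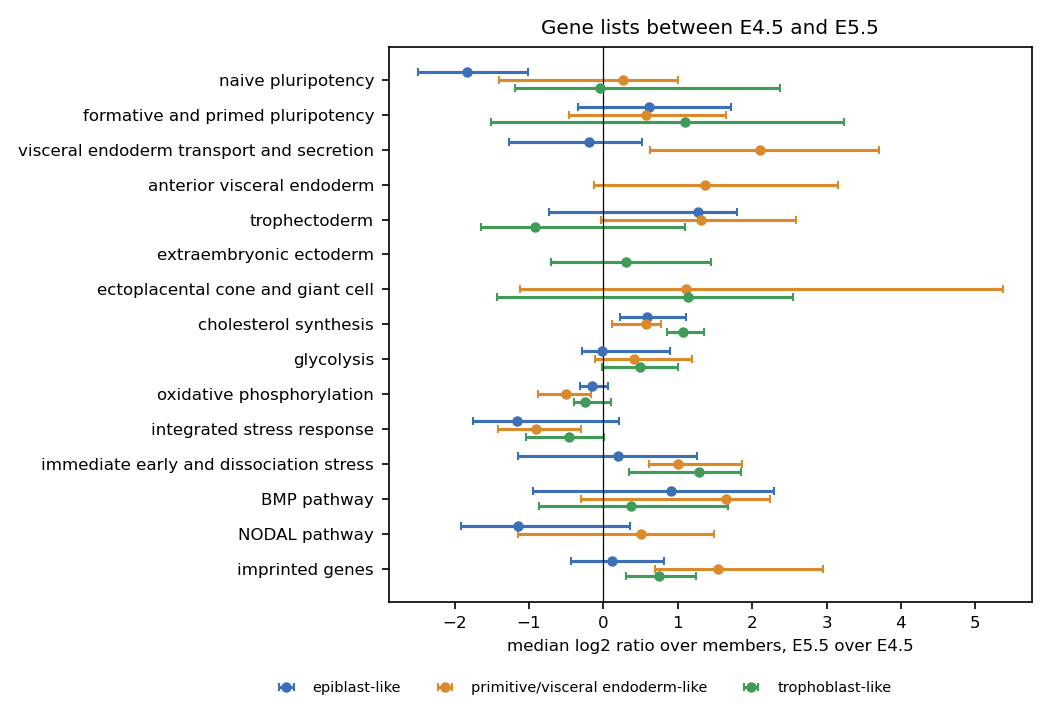
Median log2 ratio of E5.5 over E4.5 (x axis) of fixed gene lists (y axis) in epiblast-like, endoderm-like and trophoblast-like cells, with the order-statistic 95% interval of the median over list members as bars. The transport list of the endoderm is at 2.10 and the naive list of the epiblast at −1.83.

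The E3.5 and E4.5 libraries, collected and filtered alike, were compared to follow the inner cell mass and trophectoderm through blastocyst maturation. The E3.5 epiblast-like class still held primitive endoderm transcripts, and the early primitive endoderm list was −3.40 [−3.82, −1.74] at E4.5 over E3.5, with 8 of 9 members at least 2-fold lower. Gata6 was 359 CPM at E3.5 and 3.77 CPM at E4.5, 95.4-fold lower. The naive list was already lower at E4.5 (−1.67 [−2.68, −0.98], 9 of 12 members) and the formative list higher (1.75 [1.09, 2.74], 12 of 13 members). Lef1, a WNT effector, had 0 counts at E3.5 and 408 CPM at E4.5, at least 108-fold higher.

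In the same class the amino acid transporter Slc38a2 was 26.5 CPM at E3.5 and 819 CPM at E4.5, Igfbp2 5.05 and 265 CPM, Tceal9 3.78 and 361 CPM, and the collagen gene Col18a1 1.26 and 182 CPM. The autophagy receptor gene Calcoco2 was 1873 and 21.4 CPM, the methyltransferase gene Bhmt 291 and 2.03 CPM, and Olfr1459, of the large olfactory receptor family, 450.3 and 6.95 CPM. Glycolysis genes were higher at E4.5 (1.04 [0.46, 2.51], 10 of 19), with Ldha, the lactate dehydrogenase subunit, at 60.5 and 822 CPM. Basement membrane genes were lower (−1.74, 7 of 11), a list that shares Lama1, Lamc1, Col4a1 and Col4a2 with the early primitive endoderm list. The integrated stress response list was 0.87 [−0.60, 2.35], with 4 of 9 members at least 2-fold higher and 1 lower. The classes rested on 44 cells and 792820 UMIs at E3.5, the median of all genes was −0.10, and when the E3.5 library was clustered alone 46 of its 88 cells lay in clusters with markers of 2 lineages.

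The trophoblast was compared between the same libraries. Dppa3 (Stella), a maternal-effect gene, was 598 CPM at E3.5 and 7.74 CPM at E4.5, and Khdc3, of the subcortical maternal complex, 821 and 23.5 CPM. Pou5f1 was 281 and 8.05 CPM, Calcoco2 1783 and 80.8 CPM and the galectin Lgals4 524 and 25.1 CPM. Higher at E4.5 were Ldha (0 counts and 708 CPM, at least 196-fold), the homeobox gene Rhox5 (2.41 and 349 CPM), Bex1 (8.44 and 486 CPM), Nppb (1.21 and 316 CPM) and Ctsll3 (1.21 and 326 CPM). The ectoplacental cone and giant cell list was 1.43 [0.31, 3.12] and glycolysis 1.09 [0.31, 2.17], with 9 of 17 members at least 2-fold higher. The trophectoderm list was −0.68 [−1.45, −0.42], and ribosome biogenesis 0.93 [0.15, 1.52]. E3.5 trophoblast was 42 cells with 829725 UMIs, and the median of all genes was 0.02.

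Between lineages of the same library, where stage and collection do not differ, cholesterol synthesis was lower in epiblast than in endoderm, by a median of −0.70 at E4.5, −1.37 [−1.54, −0.91] at E5.0 (12 of 17 members at least 2-fold lower) and −0.63 [−1.14, −0.26] at E5.5. The medians of all genes for that pair were −0.04, −0.22 and −0.23. At E4.75 the interval included 0 (−0.45 [−0.75, 0.29]). Endoderm exceeded trophoblast in the same genes at E4.5 (0.76 [0.57, 1.11]) and E5.0 (0.58 [0.43, 0.87]), against 0.13 and 0.28 for all genes, but at E5.5 the interval, 0.39 [−0.12, 0.91], included the 0.25 of all genes. S phase genes were higher in epiblast than in endoderm (0.63 at E4.5, 0.54 at E5.0, 0.43 at E5.5) and than in trophoblast (0.68, 0.41 and 0.33, against 0.06, 0.01 and −0.01 for all genes), although against trophoblast the intervals at E3.5 (0.82 [−0.0021, 1.02]) and E5.25 (0.30 [−0.03, 0.53]) included 0. Immediate early genes were lower in epiblast than in trophoblast at E5.0 (−1.50 [−2.94, −0.67]) and E5.5 (−1.72 [−3.43, −0.38]), while at E4.5 and E4.75 the intervals included 0 (−0.91 [−1.90, 0.84] and −1.09 [−3.08, 0.35]), with 8 of 11 members at least 2-fold lower at E5.5. Imprinted genes were lower in epiblast than in endoderm at E5.5 (−1.28 [−1.95, −0.54], 9 of 15 members at least 2-fold lower, with the class marker of the list left out), while members went both ways at E4.5 (0.61 [−1.54, 1.66]) and E5.0 (−0.72 [−2.26, 1.41]).

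Some genes differed in the same direction in epiblast, endoderm and trophoblast between E4.5 and E5.5. Xist was higher in each, at 46.4 and 944 CPM in epiblast, 293 and 1180.3 CPM in endoderm and 179 and 741 CPM in trophoblast. Its log2 ratios of E5.25 over E4.75 were 2.04, 0.85 and 0.38 in that order. The sex of the pooled embryos was not examined. The small GTPase gene Arf5 had log2 ratios of 2.19, 1.79 and 1.72 (0.50, 0.23 and 0.26 in E5.25 over E4.75), the BMP target Id1 1.76, 1.66 and 1.67 (but −0.68, 0.18 and −0.22 in E5.25 over E4.75), the tRNA splicing subunit Tsen34 1.86, 2.12 and 1.65 (0.30, 0.53 and 0.15), and the glycolytic enzyme Pgam1, which has processed copies, 1.95, 1.70 and 1.99 (0.42, 0.41 and 0.56). Lower in each were Spata7 (log2 ratios of −2.97, −3.04 and −3.29), Olfr655, Ubash3a, Ppm1e and Adam2. Spata7 was 895 CPM in E4.5 epiblast and 105 CPM at E5.5, with nearly the whole difference between the flushed E4.5 and the dissected E4.75 library.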

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

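Of the tests in this part, those on pairs of cells and on free RNA in single clusters were chosen only after the result was seen, and the test of free RNA over all clusters before it.

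Upp1, which splits uridine into uracil and ribose phosphate, differed in opposite directions between lineages: its log2 ratio of E5.5 over E4.5 was 2.79 in trophoblast-like and −3.43 in epiblast-like cells, in single libraries, so the difference was not tested. Uterine epithelium-like cells, maternal by their markers and not used in the comparisons, were 1.44% of cells at E4.75, 0.399% at E5.0 and 0.461% at E5.25, the unfiltered libraries, against 1 of 961 cells at E4.5 and 0 of 8102 at E5.5, which allows up to 0.0370%. Their cluster also reached 0.402 of its marker score for trophoblast.

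Cells with markers of 2 lineages were 1.16% at E4.75, 1.62% at E5.0, 1.61% at E5.25 and 13.7% at E5.5, where alternatives gave 3.16% (at least 2500 detected genes) to 16.8% (no doublet removal, which gave 2.43%, 5.01% and 3.69% in the earlier libraries). Pairs of cells of the depth of kept cells are argued against as the main source of those left at E5.5 after doublet removal. Of these, 31.6% [28.9, 34.5] lay above the median UMIs of the kept cells of the library. The test does not cover cells that doublet removal took out. It does not hold for the earlier libraries either. There the median depth of such cells was 1.83, 1.73 and 1.33 times that of the library at E4.75, E5.0 and E5.25, against 0.726 at E5.5. Pairs of cells that each had few counts stay open as an explanation, since the test made for them cannot decide it. The median of 3703 UMIs was 0.684 of that of random pairs of E5.5 barcodes (5417 UMIs), near the lower end of the range of 0.67 to 1.5 set for it. These pairs joined barcodes of any depth, and the 15092 of 20000 that reached the minimum of genes for kept cells were used. Only 21.6% of pairs reached it with both barcodes below it, so 5417 UMIs is not the depth of pairs of shallow cells. The test also does not set pairs apart from single cells, since the median of all kept cells, 5104 UMIs, lies in the range too. For free RNA of the whole library, the level of the remaining lineage was set against that of the lesser of the 2 lineages. The test set beforehand needed a ratio below 0.25 in each cluster tested. The highest ratio was 0.279, so that test could not decide. Taken singly, a split made after the result, clusters 13 and 18 stood at 0.169 [0.150, 0.190] and 0.133 [0.116, 0.154]. These ratios argue against free RNA of the whole library as the only source there. A low remaining lineage is partly built in, since the clusters were set apart by their 2 highest marker scores. Cluster 17 (303 cells), at 0.279 [0.236, 0.336], spans the bound of 0.25, so free RNA cannot be told apart there. No biological explanation was tested.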

How the results depend on the processing

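The alternatives that keep mixed clusters, correct for gene length or exchange a stage were chosen after seeing the data. Of 48 alternative values of class shares 35 stayed within the counting interval, of 912 values of named genes 692 and of 28 per-cell shares 22. Of 96 values of the main list medians 95 and of 1215 values of other list medians 1189 stayed within the interval over list members, which is often wide enough to hold a change of sign. Of the named gene ratios 45 of 48 moved with E4.75 in place of E4.5, 57 of 68 with a pseudocount of 1 CPM, 32 of 68 with a total without mitochondrial and ribosomal protein genes and 24 of 48 with E5.25 in place of E5.5. At E5.5 the epiblast, endoderm and trophoblast with giant cell shares were 25.6%, 13.6% and 38.3% at 1000 detected genes and 33.3%, 18.5% and 42.6% at 2500. Without doublet removal the epiblast share was 27.7% and the endoderm share 14.6%. At resolution 0.5 the endoderm share was 14.3% and that of trophoblast with giant cells 44.0%, with each library clustered alone the endoderm share was 14.5%, and with mixed clusters kept they were 25.9% and 39.6%. Cer1 and Dkk1 shares at 2500 genes were 4.19% and 13.8%, and thinned to 6000 UMIs the Hhex, Lefty1, Cer1 and Dkk1 shares were 21.4%, 10.2%, 8.36% and 28.5%, as deeper cells show more. The epiblast naive pluripotency median log2 ratio was −3.00 against −1.83 with a pseudocount of 1 CPM, which damps ratios less. Of values whose interval excluded 0, directions reversed for endoderm Pou5f1, 0.032 at 2500 genes against −2.18, and for endoderm oxidative phosphorylation, 0.032 against −0.50 with E4.75 in place of E4.5; the cause was not tested. Lists with an interval that included 0 changed sign too, such as the epiblast formative and primed pluripotency median log2 ratio, 0.62, at −0.084 with E4.75 in place of E4.5, and the trophoblast extraembryonic ectoderm median log2 ratio, 0.31, at −0.046 with that exchange and −0.13 with members at 50 CPM or more. Parietal endoderm-like cells at E4.75 numbered 17 at 1000 genes, 14 at 2500 genes, 14 with at most 8% mitochondrial counts and 23 without doublet removal, against 209. No paired analysis was possible because each stage is 1 library. The E3.5 library (88 cells) limits all values at that stage, and the depth of E5.5 cells limits per-cell shares.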

Other observations

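All tests reported in this part were chosen only after the result was seen, as were the genes named in its first paragraphs, which come from the fixed lists and markers.

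Giant cell-like cells held more of 4 genes that vessels also use than other trophoblast of the same library did. Of these, Pecam1 and Esam are in the fixed endothelium markers, and Thbd and Tfpi in the parietal endoderm markers. In giant cell clusters 9 and 15, 3 endothelium markers each stood at 2-fold or more over the mean of clusters, while most of that fixed list did not. In trophoblast cluster 22, 2 endothelium markers did so, and Cdh5 was among its leading genes as in the giant cell clusters. The other endothelium markers were not compared with trophoblast, and RNA from maternal vessels was not tested. At E5.25 the adhesion molecules Pecam1 (134 against 4.31 CPM) and Esam (121 against 2.85 CPM) and the clotting inhibitors Thbd (68.1 against 1.99 CPM) and Tfpi (211 against 11.1 CPM) were higher in giant cells. The trophoblast regulators Cdx2, Esrrb and Id2 were lower in them, with Cdx2 at 3.33 against 64.5 CPM, Esrrb at 1.57 against 35.7 CPM and Id2 at 106 against 898 CPM. The order was the same at E5.0 and E5.5. In the E5.5 library, where most giant cells lay in cluster 9 and not in cluster 15, they also held 105 CPM of the epiblast marker Pou5f1, against 20.6 CPM at E5.25.

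In parietal endoderm-like cells the uptake receptors Cubn and Lrp2 were lower at later stages, as they were in visceral endoderm. Parietal Cubn was 4580 CPM at E4.75, 3068 CPM at E5.0, 2013 CPM at E5.25 and 782 CPM at E5.5, and its partner Lrp2 3212, 2008, 1683 and 739 CPM. In visceral endoderm Cubn was 4877 CPM at E4.75 and 2226 CPM at E5.5, and Lrp2 5003 and 1458 CPM. Nidogen Nid1, a linker of the basement membrane, was 133 CPM in parietal cells at E4.75, 344 CPM at E5.0, 571 CPM at E5.25 and 529 CPM at E5.5, against 76.1 CPM in visceral endoderm at E5.5. The E4.75 values rest on a split from endoderm that 4 alternatives hardly made (14 to 23 parietal cells there instead of 209), and the E5.5 values on another mix of clusters, as 176 of 421 cells lay in cluster 23. Parietal Cubn at E5.5 was 778 CPM without doublet removal, 1560 CPM at 2500 genes and 1626 CPM with each library clustered alone. The E5.25 values of these settings were 1812, 2017 and 2164 CPM.

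A set of 16 genes, among them Spata7, Adam2 and Ubash3a, stood at 50 CPM or more at E4.5 and at a log2 ratio of −2 or lower at E5.5 in epiblast, endoderm and trophoblast alike. Free RNA of the E4.5 library is argued against as the only source of the counts of all these genes. The log2 ratio of epiblast to trophoblast at E4.5 had an interquartile range over them of 0.919, against 0.0868 from counting error. Free RNA as part of the counts, or for some of the genes, is not excluded by this. The check on gene length cannot decide, since the genes were picked at −2 or lower. Over the same stages, genes grouped by length had median log2 ratios of only −0.38 (epiblast) to 0.31 (endoderm). Taking off values this small could not remove a difference picked for its size. The median log2 ratio was −2.78 after this, against −2.72 before. The values show only that the shift shared by genes of like length was small beside the difference. A difference in collection or library between flushed and dissected embryos cannot be told apart from stage. As a median over genes and classes, 0.905 of the difference was present at E4.75, against 0.348 for 77 genes that differed in 1 lineage. Of the 16, Hist1h1b fell mostly later, at 372, 283 and 72.8 CPM in epiblast at E4.5, E4.75 and E5.5. In trophoblast it was 228, 205 and 40.7 CPM. A change with stage in all lineages stays open and untested.

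The median of the integrated stress response genes was higher at E4.5 than at E5.5 in endoderm (log2 of E5.5 over E4.5 −0.91 [−1.41, −0.30]), while the intervals included 0 in epiblast (−1.16 [−1.76, 0.21]) and trophoblast (−0.46 [−1.03, 0.0022]). The immediate early list was higher at E5.5, with an interval above 0, in 2 of 3 classes (endoderm and trophoblast). In these it argues against a stress of dissociation at E4.5 that raised both lists, unless immediate early genes also rise with stage, which was not tested. Such a stress stays open for the epiblast, where that interval included 0. A stress that raised only the integrated stress response genes stays open in all classes. An effect of flushing and superovulation of equal size at E3.5 and E4.5 is argued against as the whole cause in trophoblast. There the median of E4.5 over E3.5 was 1.17 [0.59, 1.93] over 9 genes, above the 0.5 set for this. The interval measures spread between genes of single libraries, with 42 trophoblast cells at E3.5. An effect of flushing that differed between the 2 libraries cannot be told apart. Flushing and superovulation cannot be told apart from stage in epiblast (0.87 [−0.60, 2.35]) or with both classes averaged (0.739 [0.433, 1.93]), whose lower ends lie under 0.5. Endoderm was too rare at E3.5 to compare. A difference that belongs to the stage itself stays open and untested.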
